A study of Mus musculus with 8 samples.

How the data were processed

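The data were expression values from 8 mouse gene arrays. Per the labels' protocols, EAE was induced with residues 35 to 55 of myelin oligodendrocyte glycoprotein in complete Freund's adjuvant and 200 ng of pertussis toxin. Mice were perfused with 25 mL of cold saline, brains and spinal cords were collected, and their cells were enriched on Percoll. Per the series' design text, cells positive for CD11c and eYFP were sorted at day 18 from spleen and from the central nervous system of bone marrow chimeras. Arrays labelled as brain are called brain here although the protocol names the spinal cord too. RNA was extracted with RNeasy Mini columns and amplified into biotin-labelled cDNA with the Nugen Ovation Pico WTA kit, per the labels' protocols.

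The deposited values are log2 expression values made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, equalises the distribution of probe intensities across the arrays processed together, and summarises the probes of a probe set. The version of RMA, its software, and which arrays were processed together are not given in the sources used here. The values ran from about 2 to 13 on every array, which fits a log2 scale, and no further transformation or filter was applied. Because such normalization sets the overall distribution of each array, a change that affects most genes at once cannot be read from these values.

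Probe sets were named from the platform annotation, which can be old. Of 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed here. Through their Entrez identifiers, 21698 of the 21789 were matched to the RefSeq genes of assembly GRCm38.p6, and 91 kept the annotation's symbol; no coordinates were used. For the 999 genes with several probe sets the one with the highest mean over all arrays was taken, which left 19938 genes. Probe sets with several or no symbols were counted only as a separate group, from a fit and adjustment over all 35556 probe sets.

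Samples were grouped by the labels: 3 sensitive spleen, 3 resident spleen, 1 sensitive brain and 1 resident brain array. Brain was compared with spleen in limma 3.58.1 (R 4.3.3, lmFit and eBayes) over all 8 arrays with origin as a covariate, which leaves 5 residual degrees of freedom. The comparisons within an origin, resident against sensitive spleen, and the interaction came from a model with 4 groups and 4 residual degrees of freedom, whose spread rests on the 6 spleen arrays. Tests were two-sided, p-values were adjusted over all genes by the Benjamini-Hochberg method, and 0.05 was the threshold. The 2 brain arrays were compared as values with no test.

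Gene lists for 21 cell types and 24 functions were written before the data were examined; 687 of their 757 symbols were matched. They were tested with camera in limma at an inter-gene correlation of 0.01, adjusted over the 45 lists, and again with an estimated correlation, with fry and on ranks. Each list's median was also set against 10000 random lists of the same size matched on spleen level, a step added after seeing the data.

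The rule for named genes took, for brain against spleen and for resident against sensitive spleen, the 8 genes with the largest difference in each direction that passed and did not overlap between the groups. Where fewer than 5 passed in a direction, it took the 5 with the smallest p. It added up to 3 members of each list with the smallest p, up to 3 microRNA genes, and the 5 largest in each direction for the other comparisons. From the genes so named, those discussed in the text were picked after their values were seen. S100a8 and S100a9 lie outside the rule, as does Itgax for brain against spleen, and they were also chosen after their values were seen; for resident against sensitive spleen the rule named Itgax. The alternatives were computed for all genes the rule named, discussed or not.

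Alternatives were every probe set, genes above the median level, eBayes with trend and robust, other scalings between arrays (cyclic loess, median centring, quantile), array weights, a log2 difference of at least 1, other models, a block on the replicate number (statmod 1.5.0 for the random block), and leaving out each array in turn. List tests after quantile normalization, the medians of lists and gene families under each scaling, and the values of the brain pair under each scaling were added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

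The gene tests were tested on simulated data with 19938 genes, 100 of them changed by 1 log2 unit and 100 by 2. For brain against spleen 82% and 95% were recovered at those sizes, with 11 false calls. In sensitive cells 23% and 88% were recovered with 5 false calls, in resident cells 31% and 87% with 11, between resident and sensitive spleen 72% and 97% with 12, and for the interaction 1% and 64% with 3. None had the wrong sign. In each of the list tests 1 of 1 shifted list was recovered among 45, with 0 false calls. These figures hold for the simulated data only. They do not measure false list calls in the real arrays, where splits of the spleen arrays that mixed the origins called 0 to 19 lists. Nor do they show recovery at the spread of real brain arrays. In the fit with array weights the brain arrays had a weight of 0.41, against 0.68 to 2.25 for the spleen arrays. The replicate numbers in the labels are shared between tissues only for sensitive arrays 5 and resident arrays 2. With 1 brain array per origin these are 2 pairs, too few to show whether the numbers pair the arrays, so no pairing was used in the main comparisons.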

Results

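The series measured mRNA levels in dendritic cells during experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis in which T cells attack myelin. Mice whose bone marrow had been replaced after irradiation were immunised with residues 35 to 55 of a myelin protein, MOG. Cells carrying the dendritic cell integrin CD11c and the yellow fluorescent reporter eYFP were sorted from spleen and from the perfused central nervous system 18 days later. Each array was labelled as radiation-sensitive, bone-marrow-derived cells (called sensitive here) or as locally derived, resident cells (called resident), and as spleen or brain. There were 3 sensitive spleen arrays, 3 resident spleen arrays, 1 sensitive brain array and 1 resident brain array. Every array gave a log2 RMA value for 35556 probe sets, of which 21789 carried 1 gene symbol and covered 19938 genes. The number of arrays limits the precision, most of all in brain, where neither origin had a replicate. The p-values measure only the spread between these arrays, which may be technical. The comparisons, the gene lists and the rule for named genes were fixed before the data were examined.

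Arrays from spleen resembled each other closely. Pearson's r across genes ran from 0.967 to 0.986 over the 15 pairs of spleen arrays and from 0.816 to 0.868 over the 12 pairs of a brain with a spleen array, and was 0.869 between the 2 brain arrays; genes are not independent replicates. The spread of values also differed by tissue. The interquartile range of gene values was 2.11 to 2.46 log2 units on the spleen arrays, 1.57 on the sensitive brain array and 1.63 on the resident brain array.

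The main question was how dendritic cells of the inflamed central nervous system differed from those of spleen. Each array measured a sorted population, so a difference may also reflect a different mix of cell types. The arrays cannot separate that from a change within dendritic cells. Ngp (neutrophilic granule protein, probe set 10589535) fell by 6.44 ± 0.10 log2 units (SE) in the brain cells, from 12.07 ± 0.05 in spleen (SD, n = 6) to 5.71 on the sensitive and 5.56 on the resident brain array (adjusted p = 1.68e-07). C3ar1, the receptor for the complement fragment C3a (probe set 10547657), rose by 5.24 ± 0.25, from 5.39 ± 0.27 in spleen to 10.98 and 10.28 in brain (adjusted p = 4.40e-05). Ccl12, a chemokine that attracts monocytes, rose by 4.77 ± 0.18 (adjusted p = 1.63e-05). The values carry no detection calls, so where the lower side of a difference may lie near background, as for Ngp in brain and C3ar1 in spleen, the difference can be read only as a lower bound. Of 24 cell cycle genes 20 fell, of 18 genes of mature dendritic cells 12 fell and 1 rose, and of 16 genes of microglia, the resident macrophages of the brain, 14 rose and 1 fell.

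Over both origins, 11948 of 19938 genes differed between brain and spleen at an adjusted p under 0.05 by limma, 8627 higher and 3321 lower in brain. Among the 2673 genes that also differed at least 2-fold the balance was the other way, with 458 higher and 2215 lower. The median gene lay 0.32 log2 units higher in brain. The share of changed genes that were higher was 72.2% with the values as deposited, 58.5% after centring each array on its median and 48.3% after cyclic loess between arrays, so the direction of small changes depended on the scaling. After sorting genes by their mean spleen level into quartiles, the median difference was 0.51 in the lowest quartile, 0.53 and 0.15 in the next quartiles and -0.79 in the highest.

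The largest rises after C3ar1 and Ccl12 included Sparc, a matrix glycoprotein gene made by microglia and astrocytes (3.88 ± 0.38), C1qa, a chain of the first complement component (3.86 ± 0.28), the melanosome and lysosome glycoprotein gene Gpnmb (3.78 ± 0.46), Cebpzos (3.73 ± 0.52) and the acute phase gene Saa3 (3.55 ± 0.51), with adjusted p-values of 1.78e-04 to 0.00182. Mcpt2, a mast cell protease gene, averaged 3.82 ± 1.20 higher (adjusted p = 0.0270) but stood at 10.36 on the resident brain array and 3.78 on the sensitive one. Its difference was 0.50 without the resident brain array and 7.14 without the sensitive one. Its call ended after cyclic loess (adjusted p = 0.0885), after quantile normalization (0.0626), without resident spleen replicate 1 (0.0505) and without resident spleen replicate 3 (0.0515). Besides Ngp, the largest falls were those of Ltf (lactotransferrin, -6.07 ± 0.12), Lcn2 (lipocalin 2, -6.00 ± 0.19), Retnlg (-5.94 ± 0.23), Camp (the cathelicidin peptide, -5.71 ± 0.16), Ifitm6 (-5.47 ± 0.21), Apol7c (-5.31 ± 0.35) and Cxcr2, a neutrophil chemokine receptor (-5.28 ± 0.17).

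**Figure D1:**
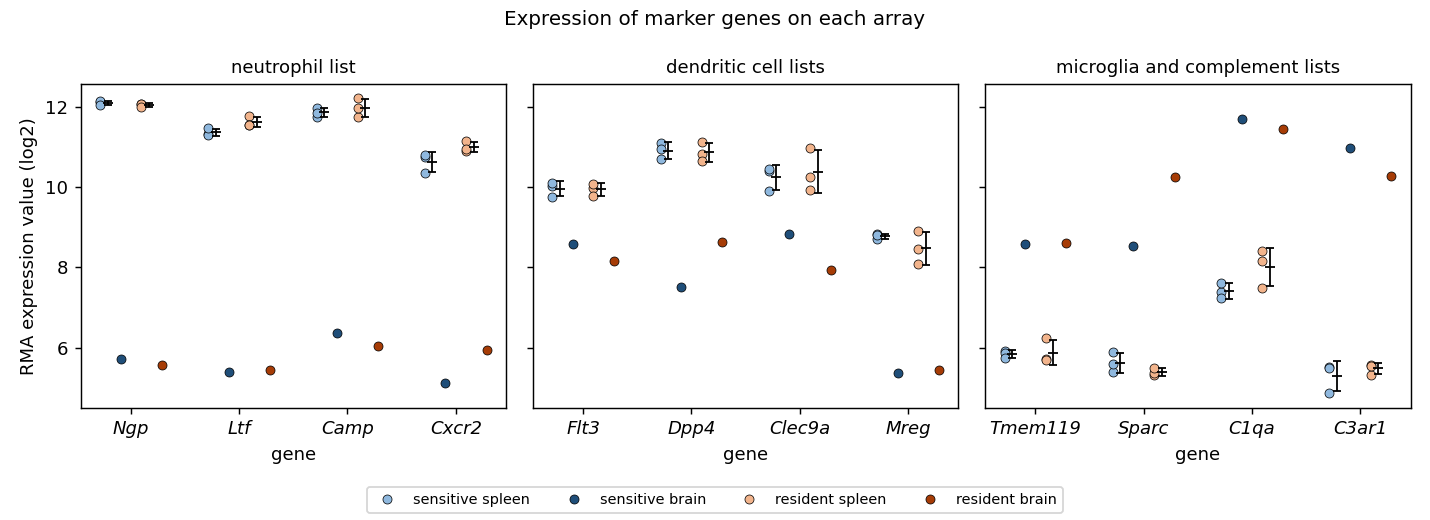
RMA expression values (log2) of 4 neutrophil genes, 4 dendritic cell genes and 4 genes of the microglia and complement lists, 1 point per array and 1 colour per group, with the mean and SD of each group of 3 spleen arrays beside its points. Ngp stood at 12.07 on average in spleen and at 5.71 and 5.56 in brain, and C3ar1 at 5.39 in spleen and 10.98 and 10.28 in brain.

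Neutrophil markers made the clearest group. Of 14 measured, 13 fell and 1 did not pass; adjusted over the list alone, 13 also fell. The list's median difference was -3.83 (camera adjusted p = 3.49e-14; adjusted p = 0.0703 with an estimated correlation). Cyclic loess left 12 lower and 1 higher, with a median difference of -3.15. The median of the list was 10.97 ± 0.22 in spleen (SD, n = 6) and 5.84 and 6.05 on the sensitive and resident brain arrays. Markers of cells of nervous tissue moved the other way by small amounts: 10 of 13 neuron genes, 10 of 12 oligodendrocyte genes and 9 of 12 astrocyte genes rose, and adjusted over the list alone 10, 10 and 10 did. After cyclic loess 3 of 13, 5 of 12 and 2 of 12 rose, and after quantile normalization 6, 7 and 6. Their medians were 0.34, 0.23 and 0.34 above that of all genes (camera adjusted p = 0.0420, 0.0236 and 0.0418; adjusted p = 0.456, 0.463 and 0.456 with an estimated correlation). After cyclic loess the neuron, oligodendrocyte and astrocyte medians were 0.13, 0.35 and 0.14 above that of all genes. With the values as deposited these lists had median spleen levels of 5.22, 5.34 and 5.45. Those levels lay in the quartile of genes from 4.89 to 5.92, of which 66.5% rose. Examples of these markers were Nefl, a neurofilament gene (1.21 ± 0.16), Mog, the myelin protein used for immunisation (0.81 ± 0.11), and Slc1a3, an astrocyte glutamate transporter gene (0.83 ± 0.10). The neuron and astrocyte calls ended after cyclic loess, after quantile normalization and without the resident brain array, the neuron call also without sensitive spleen replicate 5, and all of these list calls without the sensitive brain array.

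Dendritic cell genes were examined as 5 lists. Of 10 genes shared by dendritic cells, 7 fell and 3 did not pass, with the same 7 of 10 adjusted over the list alone; the median was -1.41 (camera adjusted p = 3.38e-05; adjusted p = 0.267 with an estimated correlation). After cyclic loess 4 fell with a median of -0.75, and after quantile normalization 5 with -0.87. Flt3, the receptor for the growth factor of dendritic cell precursors, fell by 1.59 ± 0.16 and the peptidase gene Dpp4 fell by 2.81 ± 0.26 (adjusted p = 5.57e-04 and 4.75e-04). Of 18 genes of mature dendritic cells, 1 rose, 12 fell and 5 did not pass, and adjusted over the list alone 1 rose and 14 fell (median -1.24, camera adjusted p = 2.03e-07; adjusted p = 0.418 with an estimated correlation). After cyclic loess 9 fell and the median was -0.80. Mreg fell by 3.22 ± 0.21, Tmem123 by 2.26 ± 0.30 and Apol7c by 5.31 ± 0.35. Markers of the cross-presenting cDC1 subset fell in 7 of 16 cases and rose in none, also adjusted over the list alone (median -0.87, camera adjusted p = 7.59e-04; adjusted p = 0.456 with an estimated correlation), a call that ended after cyclic loess. After that scaling and after quantile normalization 5 and 6 fell, with a median of -0.54 under both. In spleen 15 of the 16 lay in the highest quartile of level, where the median was -0.79 and 2540 of 4985 genes fell, and the list's median lay at percentile 36.3 of 10000 random lists matched on spleen level. Clec9a, a receptor for dead cells, fell by 1.93 ± 0.33. Among 12 cDC2 markers 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.554), and 1 fell after cyclic loess or quantile normalization; the lectin genes Mgl2 and Clec10a rose by 1.74 ± 0.22 and 1.66 ± 0.31. Of 12 markers of plasmacytoid dendritic cells 3 rose and none fell, also adjusted over the list alone; the median was -0.01 and the mean 0.04, while the test pointed down (camera adjusted p = 0.688). After median centring 1 rose, and after cyclic loess and quantile normalization 3 and 4 rose and 1 fell. Itgax, which encodes CD11c and was singled out after its values were seen, fell by 1.99 ± 0.32 (adjusted p = 0.00245), from 9.79 ± 0.17 in spleen (SD, n = 6) to 8.53 and 7.08 in brain.

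Most microglia genes rose. Of 16 measured, 14 were higher, 1 was lower and 1 did not pass, and adjusted over the list alone 15 were higher and 1 lower (median 1.34, camera adjusted p = 5.84e-04; adjusted p = 0.267 with an estimated correlation). Tmem119, a membrane protein gene used to mark microglia, rose by 2.73 ± 0.16 to 8.57 and 8.60 (adjusted p = 8.78e-05), Fcrls by 2.09 ± 0.18 and Olfml3 by 1.35 ± 0.12. Genes of disease-associated microglia, 12 of whose 17 members stand on other lists too, rose in 13 cases and fell in 1, with the same counts adjusted over the list alone (median 1.20, camera adjusted p = 0.0420; adjusted p = 0.463 with an estimated correlation). Without the sensitive brain array or without resident spleen replicate 2 that list no longer passed. Apoe, a lipid carrier, rose by 3.26 ± 0.25 and Trem2, a lipid-sensing receptor gene, by 1.20 ± 0.11 (adjusted p = 2.27e-04 and 5.17e-04). Red pulp macrophage markers gave 4 higher and 2 lower of 14, also adjusted over the list alone (camera adjusted p = 0.725); the 3 C1q chain genes C1qa, C1qb and C1qc rose by 3.86 ± 0.28, 2.65 ± 0.21 and 2.81 ± 0.23. Monocyte markers split, with 4 of 14 higher and 5 lower, also adjusted over the list alone. The monocyte median was 0.38 and the mean 0.05 while the test pointed down (camera adjusted p = 0.367); after cyclic loess and quantile normalization 6 rose, and 3 and 5 fell. Fcgr1, a high-affinity antibody receptor gene, rose by 2.82 ± 0.29 and Ccr2, the receptor for Ccl2, by 2.25 ± 0.32, while Ifitm6 fell.

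The lists of complement, phagocytic receptor and lysosome genes did not pass. Of 12 complement genes 7 rose and 3 fell, of 21 phagocytic receptor genes 11 rose and 1 fell, and of 22 lysosome genes 8 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.629, 0.198 and 0.282), while 43.3% of all genes rose. Against random lists matched on spleen level their medians of 0.58, 0.76 and 0.42 lay at percentiles 99.9, 100 and 100. The scaling moved these values: after cyclic loess 8 phagocytic receptor genes rose and 2 fell, with a median of 0.26, and 13 lysosome genes rose and none fell, with a median of 0.96. After quantile normalization 13 lysosome genes rose and 1 fell, with a median of 0.71, and after median centring the lysosome median was 0.26. Lamp1, a lysosomal membrane protein gene, rose by 1.36 ± 0.14, while the scavenger receptor gene Cd36 fell by 3.35 ± 0.40. Chemokine genes rose in 11 of 20 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 0.204). Ccl2 rose by 0.99 ± 0.13 and Ccl7 by 1.25 ± 0.18. Of 16 chemokine receptor genes 4 rose and 6 fell, also adjusted over the list alone (median -0.82, camera adjusted p = 0.0236; adjusted p = 0.303 with an estimated correlation), a call that ended after cyclic loess and without either brain array. Ccr7, which guides dendritic cells to lymph nodes, fell by 2.18 ± 0.34 (adjusted p = 0.00225). Adhesion genes gave 5 higher and 9 lower of 25, and 4 and 9 adjusted over the list alone (median -0.66, camera adjusted p = 0.0232; adjusted p = 0.456 with an estimated correlation), a call that ended after cyclic loess and quantile normalization. Its median was -0.15 without the sensitive brain array, -0.06 after cyclic loess with 2 genes higher and 3 lower, and -0.18 after quantile normalization with 3 higher and 4 lower. Itga4, the integrin chain through which leukocytes enter the inflamed brain, fell by 3.49 ± 0.29, and Itgb5 rose by 2.01 ± 0.30. The cytokine genes Tnf, Il12b and Il18 fell by 1.73 ± 0.31, 1.43 ± 0.19 and 1.64 ± 0.25, in a list of 19 with 5 higher and 4 lower (camera adjusted p = 0.282) and 4 and 4 adjusted over the list alone. After cyclic loess and median centring 2 of that list were higher and 4 lower.

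The balance of antigen presentation genes depended on the scaling. Of 12 genes of MHC class II presentation, 2 rose and 2 fell, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.169); the list's median was 11.11 ± 0.17 in spleen (SD, n = 6) and 10.98 and 10.99 in brain. After cyclic loess 3 rose and none fell and the median difference turned from -0.22 to 0.14; 3 rose and 1 fell after quantile normalization, and 2 and 4 after median centring. Lgmn, a lysosomal protease gene, rose by 1.62 ± 0.19 and Ctss by 0.56 ± 0.11. H2-Oa, a chain that restrains peptide loading, fell by 1.43 ± 0.31, a call lost after cyclic loess (adjusted p = 0.0629) and without the sensitive brain array (-0.73, adjusted p = 0.0579). Of 12 MHC class I presentation genes 3 fell and none rose, and 2 fell adjusted over the list alone; the list passed downwards (median -0.14, camera adjusted p = 0.0362; adjusted p = 0.456 with an estimated correlation), but its median turned to 0.37 after cyclic loess, with 4 higher and 2 lower, and 0.24 after quantile normalization, with 3 and 2. Its call ended under both scalings and without the resident brain array, where the median was -0.02; without the sensitive brain array it was -0.37. Among 17 costimulation and checkpoint genes 3 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.109), 1 and 2 did after cyclic loess and 2 and 2 after quantile normalization; Cd80 fell by 1.96 ± 0.35 and Cd274, which encodes the checkpoint ligand PD-L1, by 1.55 ± 0.23.

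Proliferation genes fell as a group. Of 24 cell cycle genes 20 fell, none rose and 4 did not pass, with 20 also adjusted over the list alone (median -1.42, camera adjusted p = 1.06e-10; adjusted p = 0.275 with an estimated correlation). Cyclic loess left 14 lower and 1 higher, with a median of -1.07. Kif11, a motor of the mitotic spindle, fell by 3.47 ± 0.18, Nusap1 by 1.93 ± 0.12 and Ccna2, which encodes cyclin A2, by 2.55 ± 0.21 (adjusted p = 5.61e-05, 9.65e-05 and 3.07e-04). Of 21 oxidative phosphorylation genes 11 fell and none rose, and 10 fell adjusted over the list alone (median -0.70, camera adjusted p = 8.28e-05; adjusted p = 0.456 with an estimated correlation). That median was -0.20 without the sensitive brain array and -0.32 after quantile normalization, with 1 gene higher and 2 lower, and -0.08 after cyclic loess, with 2 higher and none lower, where the list did not pass and the calls of Cox5a, Uqcrc2 and Ndufv1 were lost (adjusted p = 0.799, 0.0681 and 0.0574). All 21 lay in the highest quartile of spleen level, whose median was -0.79, and the list's median lay at percentile 52.4 of the level-matched random lists. Immediate early and dissociation stress genes gave 2 higher and 6 lower of 20, and 1 and 4 adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.456 with an estimated correlation), in which Zfp36 fell by 1.56 ± 0.11 and Dusp1 fell by 2.74 ± 0.25. The list's call ended after cyclic loess and quantile normalization, where the balance turned to 4 higher and 2 lower and to 5 and 2, and without the sensitive brain array.

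The title of the series concerns microRNAs, so genes of microRNA processing and the microRNA genes themselves were examined. Of 19 biogenesis genes 1 rose and 10 fell, also adjusted over the list alone (median -0.50, camera adjusted p = 8.28e-05; adjusted p = 0.303 with an estimated correlation), a call that ended among genes above the median level. Cyclic loess left 7 lower and 0 higher, with a median of -0.53. Dicer1, the enzyme that makes mature microRNAs, fell by 1.57 ± 0.26 (adjusted p = 0.00279), Tut4, which adds uridines to microRNA precursors, fell by 2.76 ± 0.21, and Tnrc6b fell by 1.21 ± 0.19. Of 296 microRNA genes 163 rose and 6 fell, but 54 and 13 did after cyclic loess, 97 and 9 after centring on array medians and 80 and 12 after quantile normalization. Their median was 0.46, which is 0.14 above that of all genes. Relative to all genes it was 0.07 after cyclic loess, 0.14 after centring on array medians and 0.08 after quantile normalization. The microRNA genes had a median spleen level of 4.39, within the lowest quartile of all genes, which ended at 4.89. In that quartile the median difference was 0.51 and 69.4% of genes rose, against 55.1% of the microRNA genes. So with the values as deposited they did not rise more, as a group, than genes of that level. Under cyclic loess 54 of the 296 rose and 13 fell, against 2216 and 2368 of all 19938 genes. The share among genes of that level was not computed under that scaling. Whether the probe sets of the microRNA genes read mature microRNAs was not examined, so their values are not read here as levels of mature microRNAs. Mir615, Mir328 and Mir212 rose by 1.10 ± 0.11, 0.81 ± 0.10 and 1.16 ± 0.14 (adjusted p = 6.00e-04, 0.00103 and 0.00115). For comparison, 799 of 1175 olfactory and vomeronasal receptor genes, which serve smell, rose and 5 fell, with a median of 0.49; after cyclic loess 62 rose and 27 fell and the median was 0.02, and after quantile normalization it lay -0.01 from that of all genes, the opposite side.

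**Figure D2:**
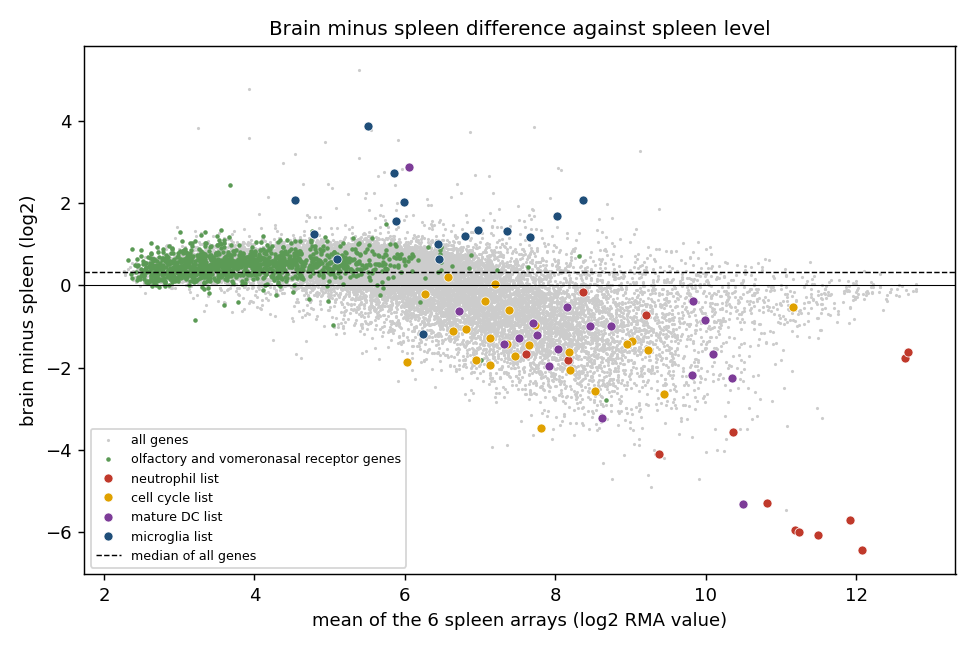
Brain minus spleen difference (log2) of each gene against its mean over the 6 spleen arrays (log2 RMA value), with the genes of 4 lists and the olfactory and vomeronasal receptor genes in colour. The dashed line marks the median gene at 0.32; the receptor genes lie at the low end with a median of 0.49, which became 0.02 after cyclic loess and -0.01 relative to all genes after quantile normalization, and the neutrophil genes have a median of -3.83.

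Of the 45 lists, 20 passed by camera with its preset correlation of 0.01, 5 upwards and 15 downwards. With an estimated correlation 0 passed (smallest adjusted p = 0.0703; 6 at an unadjusted p under 0.05), and fry, which asks only whether a list's genes move together in 1 direction, called 28. Without the sensitive brain array 13 passed. Ribosomal protein genes were a list that passed downwards (camera adjusted p = 0.0226; adjusted p = 0.463 with an estimated correlation) although 0 of 16 genes passed in limma, also adjusted over the list alone (1 at an unadjusted p under 0.05), and 6 fell after median centring. The median of -0.14 turned to 0.14 after cyclic loess; the call ended there, after quantile normalization, among genes above the median level and without the sensitive brain array. Medians were also placed among random lists matched on spleen level. Of the lists that passed downwards, neutrophil and cell cycle genes lay at percentile 0, chemokine receptors at 0.24, mature dendritic cells at 2.60, erythroid genes at 2.70, adhesion genes at 3.12 and shared dendritic cell genes at 3.35. Cholesterol synthesis lay at 8.69, microRNA biogenesis at 19.6, cDC1 at 36.3, oxidative phosphorylation at 52.4, immediate early genes at 58.4, oxidative stress at 86.4, ribosomal proteins at 98.4 and MHC class I presentation at 98.7. Of those that passed upwards, both microglia lists lay at 100, astrocyte genes at 93.6, neuron genes at 92.0 and oligodendrocyte genes at 87.9.

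Each origin was also compared with its own spleen group. Each brain group had 1 array, which was assumed to vary like the spleen arrays, so the errors and p-values include no spread measured in brain and cannot separate tissue from a deviation of that array. In sensitive cells C3ar1 and Ccl12 rose by 5.68 ± 0.28 and 4.45 ± 0.21, and Mir99a, a microRNA gene, and Gm8479 by 6.89 ± 0.61 and 5.79 ± 0.27. Gpnmb rose from 5.48 ± 0.13 in sensitive spleen (SD, n = 3) to 10.47 in sensitive brain. Ngp, Retnlg, Ltf, Lcn2 and Cxcr2 fell by 6.38 ± 0.14, 6.36 ± 0.25, 5.96 ± 0.16, 5.62 ± 0.19 and 5.51 ± 0.21. In resident cells Mcpt2, the B cell chemokine gene Cxcl13, Ccl12, Tmem37 and Sparc rose by 7.14 ± 0.16, 5.44 ± 0.18, 5.10 ± 0.21, 5.08 ± 0.18 and 4.86 ± 0.21. Ngp, Lcn2, Ltf, Camp and Anp32e, a histone chaperone gene, fell by 6.49 ± 0.14, 6.38 ± 0.19, 6.19 ± 0.16, 5.93 ± 0.20 and 5.77 ± 0.27. All these adjusted p-values lay between 1.04e-05 and 7.04e-04.

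By that test 9183 genes passed in sensitive cells (6252 higher, 2931 lower; 1136 and 2366 of them at least 2-fold), and 8863 in resident cells (6106 higher, 2757 lower; 757 and 2180 at least 2-fold). The share higher fell from 68.1% to 49.4% after cyclic loess and 53.0% after centring on medians in sensitive cells, and from 68.9% to 43.4% and 47.7% in resident cells. In a fit of the resident arrays alone 5382 genes passed. Lists of neutrophil, cell cycle, mature and shared dendritic cell genes passed downwards and the microglia list upwards in both origins (microglia camera adjusted p = 9.99e-05 in sensitive and 0.00210 in resident cells; adjusted p = 0.393 and 0.520 with an estimated correlation). With an estimated correlation 0 of 45 lists passed in either origin (smallest adjusted p = 0.393 in sensitive and 0.515 in resident cells; 3 and 2 lists at an unadjusted p under 0.05). Both origins shared 3727 genes called higher, against 1915 for independent lists, and 1692 called lower, against 405. The 2 sets of calls are not independent, because both comparisons divide by the same spread of the spleen arrays. Both brain arrays also had the narrower range of values, so the excess alone cannot be read as a shared response of the cells. Among calls of at least 2-fold, 155 higher genes were shared, of 1136 in sensitive and 757 in resident cells, and 1260 lower genes, of 2366 and 2180. Another 157 genes were called in opposite directions, 78 of them at least 2-fold in both origins, and r between the tissue differences was 0.65 across genes, which are not independent replicates.

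Whether the tissue difference itself depended on origin was tested as an interaction. With 1 brain array per origin, and a spread taken from the spleen arrays, this test cannot separate origin from a deviation of a single brain array. It passed for 755 genes, 422 with a higher and 333 with a lower difference on the resident side; 749 of them differed at least 2-fold. In 270 of the 755 genes 1 brain array lay over 2 log2 units below its spleen group while the other lay within 1 of its own. The largest positive values were those of Mcpt2 (6.64 ± 0.23, adjusted p = 3.74e-04), the kinesin gene Kif1c (6.44 ± 0.41, adjusted p = 0.00275), Fryl (6.28 ± 0.69), Sh3pxd2a (5.83 ± 0.58) and the small nucleolar RNA gene Snora31 (5.72 ± 0.33). The largest negative ones were those of Mir99a (-6.60 ± 0.87, adjusted p = 0.0116), Gm8479 (-5.61 ± 0.38), Snord49b (-5.48 ± 0.96), B230307C23Rik (-5.15 ± 0.57) and A630089N07Rik (-5.13 ± 0.44). Snord49b no longer passed without sensitive spleen replicate 1 (adjusted p = 0.0676) or without resident spleen replicate 3 (0.0611). Its difference stayed at -5.41 and -5.53 in those fits. No list passed (0 of 45 by camera; 1 at an unadjusted p under 0.05 with an estimated correlation, and 0 by fry), and 34 of the 755 genes stood on a list. The count was 493 without sensitive spleen replicate 1 and 2029 after quantile normalization.

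**Figure D3:**
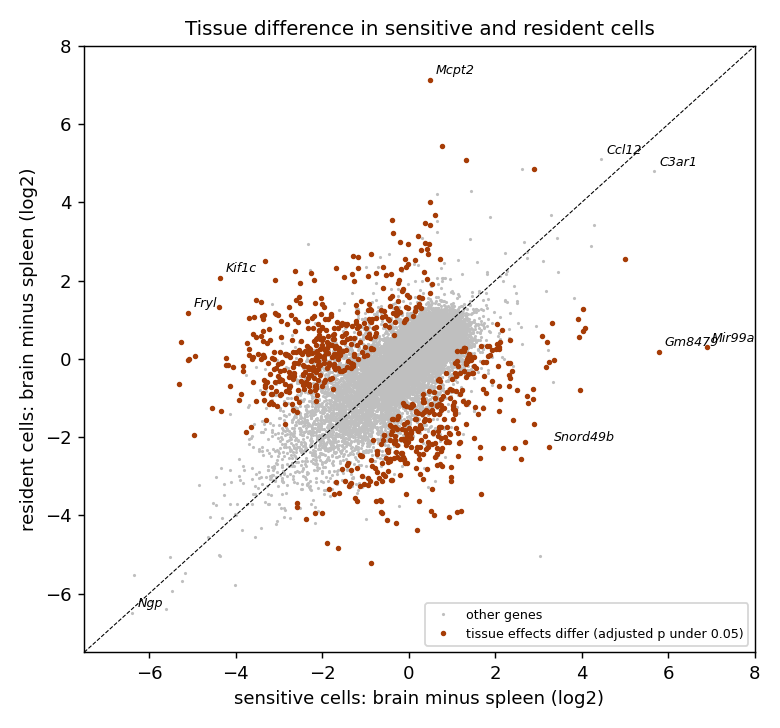
Brain minus spleen difference (log2) in resident cells against that in sensitive cells, 1 point per gene, with the 755 genes that passed the interaction test in colour and the line of equal differences dashed. Ngp lies near that line at -6.38 and -6.49, and Mcpt2 away from it, with a difference of 7.14 in resident cells.

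The 2 brain arrays, neither of which had a replicate, were set side by side as values, and no test was run. Among genes above the median level, the sensitive array was higher for Atxn1 by 6.47, Snord49b by 5.73, Scarna17 by 5.20, B230307C23Rik by 5.12 and A630089N07Rik by 5.11. Fryl, Kif1c, Sh3pxd2a, Rbm12b2 and Snora31 differed by -6.18, -5.95, -5.80, -5.66 and -5.57. Atxn1 also varied within sensitive spleen, at 6.86 ± 2.63 (SD, n = 3).

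Resident and sensitive cells of the spleen, the comparison with replicates on both sides, did not differ in any gene past the threshold. By limma 0 of 19938 genes passed (smallest adjusted p = 0.881) and 1049 had an unadjusted p under 0.05. In resident spleen all values lay above those of sensitive spleen for 926 genes and below them for 1406, together 11.7%, where chance gives 10%. Fgd4, a regulator of the small GTPase Cdc42, had the smallest p among higher genes, with a difference of 1.37 ± 0.20, followed by Ncoa4, which delivers ferritin for breakdown, at 0.69 ± 0.10. Among lower genes F420014N23Rik stood at -0.68 ± 0.11 and the respiratory chain gene Ndufa7 at -0.66 ± 0.11.

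By camera 16 of 45 lists passed in resident against sensitive spleen, all 16 upwards, although 0 genes passed over all genes. Red pulp macrophage genes had a median of 0.67 over 14 genes (camera adjusted p = 1.04e-05; adjusted p = 0.465 with an estimated correlation), complement genes 0.37 over 12 (1.77e-04; adjusted p = 0.465 with an estimated correlation) and oxidative phosphorylation genes 0.23 over 21 (1.48e-04; adjusted p = 0.470 with an estimated correlation). Without resident spleen replicate 3 the red pulp macrophage median was 0.36 (camera adjusted p = 7.67e-04); on that array the median level of the list was 8.06, against 6.97 and 7.20 on the other resident and 6.67 to 6.89 on the sensitive spleen arrays. Adjusted over the list alone, 0 genes of these 3 lists passed, against 1 of 14 monocyte and 1 of 21 phagocytic receptor genes. Adgre4, a macrophage receptor gene, differed by 1.46 ± 0.35, the mannose receptor gene Mrc1 by 1.15 ± 0.36, Apoe by 1.02 ± 0.26, the monocyte gene Cd14 by 1.09 ± 0.24 and the iron exporter gene Slc40a1 by 0.78 ± 0.26, each with an adjusted p of 0.891. The neutrophil list, with 0 genes past the threshold, had a median of 0.13 (camera adjusted p = 0.00279; adjusted p = 0.465 with an estimated correlation), a call that ended after cyclic loess and without sensitive spleen replicate 4 (median 0.04). Its median was 0.06 without resident spleen replicate 2 and 0.23 without sensitive spleen replicate 1. The oxidative phosphorylation call ended without resident spleen replicate 3 (median 0.12), and its median was 0.14 without sensitive spleen replicate 4, 0.13 after cyclic loess and 0.12 after quantile normalization. The neutrophil median after cyclic loess was 0.05. With an estimated correlation 0 lists passed (3 at an unadjusted p under 0.05), fry called 0, and 7 passed without resident spleen replicate 3.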

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

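The test of the tissue difference between origins was planned; the test of probe sets without a gene symbol of their own was chosen after the data were seen.

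The interaction test, which asks whether the brain minus spleen difference depends on origin, passed for 755 genes. It rests on 1 brain array per origin and the spread of the spleen arrays, so it cannot separate origin from a deviation of a single array. The differences, resident minus sensitive, were 6.64 for Mcpt2, 6.44 for Kif1c, 6.28 for Fryl, 5.83 for Sh3pxd2a and 5.72 for Snora31. They were -6.60 for Mir99a, -5.61 for Gm8479, -5.48 for Snord49b, -5.15 for B230307C23Rik and -5.13 for A630089N07Rik. Without sensitive spleen replicate 1 the count was 493, and Snord49b no longer passed there (adjusted p = 0.0676) or without resident spleen replicate 3 (adjusted p = 0.0611). The difference for Snord49b stayed at -5.41 and -5.53 in those fits. In 270 of the 755 genes 1 brain array lay over 2 log2 units below its spleen group while the other lay within 1 of its own (170 low on the sensitive array, 100 on the resident array), and in 62 genes 1 array lay as far above (31 on each). The median spleen level of the 755 genes was 8.24, against 5.92 for all genes. The source of these values was not examined.

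Probe sets with several gene symbols or none, which no comparison used, also differed between brain and spleen. Of 13767, 5128 passed the threshold, 3609 higher and 1519 lower in brain, with 592 higher and 1234 lower by at least 2-fold.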

How the results depend on the processing

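Tests of the lists after quantile normalization, the medians and counts of lists and gene families under other scalings, the lists matched on spleen level and the brain pair's values under other scalings were chosen only after the results were seen; the other alternatives were planned. The causes of the changes below were not tested, except where fewer genes, fewer arrays or a stricter threshold make a count smaller by construction.

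Brain against spleen (11948 genes) gave 4693 among genes above the median level, 4584 after cyclic loess, 7721 after quantile normalization, 7275 with array weights and 2673 at a log2 difference of at least 1. Leaving out each array gave 8863 to 11995. With the replicate number as a fixed block, which leaves 1 residual degree of freedom, 0 genes passed in limma (6056 at an unadjusted p under 0.05, smallest adjusted p = 0.0894), and as a random block 11754 passed (estimated correlation within blocks -0.222). Over all genes, resident brain 2 had r = 0.868 with resident spleen 2, against 0.852 and 0.853 with the others, and sensitive brain 5 had 0.833 with sensitive spleen 5, against 0.832 and 0.833. These 2 pairs are too few to show whether the numbers pair the arrays. In sensitive cells (9183) the counts were 3906 above the median level, 3910 after cyclic loess and 3502 at a difference of at least 1. In resident cells (8863) they were 3792, 3254 and 2937 for those settings, 5725 after median centring and 5382 with the resident arrays alone. Leaving out each array that could be left out gave 6779 to 9814 in sensitive and 6008 to 9749 in resident cells. Neither comparison could be fitted without its own brain array. Without the brain array of the other origin the counts stayed at 9183 and 8863 by construction. The interaction (755) gave 2029 after quantile normalization and 493 without sensitive spleen replicate 1 up to 701 without resident spleen replicate 2; it could not be fitted without either brain array. Resident against sensitive spleen gave 0 genes under every alternative run.

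Lists for brain against spleen (20) came to 0 with an estimated correlation and 8 among genes above the median level, and 13 (without sensitive brain replicate 5) to 20 without each array. For resident against sensitive spleen (16) they came to 0 with an estimated correlation, 0 by fry and 8 above the median level, and 7 (without resident spleen replicate 3) to 20 without each array.

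Of the 137 genes named for brain against spleen 131 passed; 96 of them passed under every alternative but the fixed block, which ended all 131 calls, and 35 lost their call under at least 1 other. All 10 named genes passed under every alternative run in each origin, and 9 of 10 for the interaction. No alternative there left out a brain array on which the comparison rests. None of the genes that changed sign had passed as reported. For brain against spleen, cyclic loess turned Rpl8 to 0.12, Rpl19 to 0.068, Kdm5d to -0.040 and Uty to -0.099, and quantile normalization turned Uty to -0.087. Rpl10a ran from -1.13 to 0.022 without each array (0.022 without sensitive brain replicate 5). For resident against sensitive spleen, the additive model turned Itgax to -0.25, Klrd1 to 0.46, Gja1 to -0.090, Cxcl13 to 0.87, Hif1a to -0.29, Birc5 to 0.36, Rps9 to 0.029 and Kdm5d to 0.052. Without each array Prdm1 ran from -0.048 to 0.73, Xist from -0.27 to 0.0050 and Kdm5d from -0.20 to 0.031.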

Other observations

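The test of neutrophils among the sorted spleen cells and the 3 tests for microglia genes were chosen after the results they bear on were seen; the other tests below were written down before their own results were known, though after other values of these data.

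Jchain, which joins antibody chains in plasma cells, fell by 4.70 ± 0.34 (adjusted p = 1.80e-04), in a plasma cell list of 8 with 1 gene higher and 1 lower, whose median was 0.11 while its mean was -0.68 and its test pointed down (camera adjusted p = 0.440); the median turned to -0.19 after cyclic loess, -0.05 after median centring and -0.02 after quantile normalization. Tfrc, the transferrin receptor, fell by 4.11 ± 0.24 (adjusted p = 8.20e-05), and the erythroid list had 3 of 7 genes lower, also adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.463 with an estimated correlation), a call that ended without the resident brain array. Of 17 oxidative stress genes 3 rose and 6 fell, and 3 and 5 adjusted over the list alone (camera adjusted p = 0.0236; adjusted p = 0.456 with an estimated correlation), but the median of -0.17 turned to 0.23 after cyclic loess and 0.02 after quantile normalization, with 6 and 6, and 5 and 6, higher and lower. Under those scalings the list no longer passed, nor did it without the resident brain array; the median was -0.09 without sensitive spleen replicate 4. Gclc and Gsr, which make and recycle glutathione, fell by 2.41 ± 0.17 and 1.92 ± 0.16.

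Cholesterol synthesis genes fell in 4 of 15 cases and rose in 0 by limma, also adjusted over the list alone (camera adjusted p = 0.0232; adjusted p = 0.448 with an estimated correlation), a call that ended without the resident brain array; Sc5d, a late enzyme of the pathway, fell by 0.92 ± 0.13. In the hypoxia and glycolysis list 3 genes rose and 3 fell of 18, also adjusted over the list alone, and its median of 0.04 and mean of -0.21 differed in sign (camera adjusted p = 0.196); the median was 0.21 after cyclic loess, 0.31 after quantile normalization and -0.12 after median centring. Pfkfb3, an activator of glycolysis, fell by 1.85 ± 0.22 and Ero1a, an oxidase of protein folding, fell by 2.98 ± 0.37. Tgfbr1, a TGF-beta receptor gene, rose by 1.68 ± 0.16, and the interleukin 10 receptor gene Il10ra fell by 1.56 ± 0.17.

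More genes were higher than lower in brain, most by under 2-fold. A compressed signal range of the brain arrays may account for part of the pattern. The 1175 olfactory and vomeronasal receptor genes had a median difference of 0.49 (bootstrap interval over genes 0.48 to 0.51). Higher expression of those genes in the brain cells stays open. Of the 8627 genes called higher, 36.3% (exact binomial 95% interval 35.2% to 37.3%) lay above 6.19 in brain, the 95th percentile there of the receptor genes. The bound of 50% set beforehand was wrong, because the level of a probe set depends on its probes' affinity and levels of different probe sets cannot be ranked.

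The median of the neutrophil list was high in every spleen array and low in both brain arrays, though not every member was low in brain. All 14 measured markers lay above 7.13, the 75th percentile of genes in spleen, but that restates the pattern and ranks different probe sets, so neutrophils among the sorted spleen cells stay open, although the gate asked for CD11c and eYFP; 3 of the 14 stand on other lists. S100a8 and S100a9, abundant neutrophil transcripts chosen here after their values were seen, stood at 12.65 ± 0.08 and 12.69 ± 0.02 in spleen (SD, n = 6) and at 10.86 and 10.91, and 10.88 and 11.27, in brain. Expression by the CD11c cells themselves cannot be told apart from this: the list's median varied over the spleen arrays 1.59 times as much as level-matched lists (0.81 to 3.72), and 6 arrays are too few to decide.

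Microglia genes were higher in both brain arrays. Compression of the signal range was argued against as the whole cause, since the list's median lay at percentile 100 of 10000 level-matched lists (95% of them between -0.20 and 0.52). For radiation-resistant microglia in the resident sort only, the resident minus sensitive difference had a median of -0.20 over the 16 genes. Its bootstrap interval over genes (-0.78 to 0.14) lay below the 0.66 that would be 50% of the resident effect. The list's median rise was 1.56 on the sensitive brain array and 1.33 on the resident one. The interval holds no spread between arrays. With 1 brain array per origin the test cannot separate origin from a deviation of a single array, so it cannot decide this. Microglia in both sorts stay open too. Over both origins 87.5% of the markers were called higher, with 14 of 16 in sensitive and 12 in resident cells, but that restates the pattern. The gate asked for CD11c and eYFP, and the sensitive cells were labelled as bone-marrow-derived. Itgax, which encodes CD11c, stands on the list of disease-associated microglia, so the gate by itself does not exclude microglia. Of the 16 genes 5 stand on other lists. Expression by dendritic cells in the tissue was not tested.

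For resident against sensitive spleen the 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For genes past the threshold in limma the real count was 0 (1049 at an unadjusted p under 0.05) and the highest other was 0; all 10 splits must give at least 0, so the count of splits says nothing here. For lists, 2 of the 10 gave at least the real count of 16, and the highest other was 19.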
